A study of Mus musculus with 60 samples.

How the data were processed

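RNA was measured in liver of 8-week-old male C57BL/6 mice after PHx or sham operation, per the labels. Operations took place at 8 to 9 am (morning) or 8 to 9 pm (night), with 3 mice per group, and polyA RNA was sequenced with a SMART-RNAseq kit on a NovaSeq instrument, per the labels. The submitters' processing notes name fastp 0.20.0 and HISAT2 2.1.0 and the genome builds mm8 and mm9, without a role or order for the builds. The read counter and the annotation are not given in the sources used here. Library ID series follow the labels: sham at 4 h carries one series, PHx at 4 h and all 24 h libraries another, 8 to 20 h another, and 28 and 32 h another.

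The time course tables were deposited as log2(value + 1) of an expression value rounded to 2 decimals, whose unit is not stated per the file headers. Back on the linear scale, the values of a library sum to 0.937 to 1.20 M, and to over 1 M in 37 of 48 libraries. In all sham libraries 173 genes are at 0, and in all PHx libraries 129. The 24 h morning against night tables were deposited as a raw count per gene, with rows of low counts removed by the authors. The 4 h PHx table is headed TPM, but its deposited signal is a read count times a constant of the gene that is the same in every library. Divided by the constants of the 24 h tables, which hold both, 100% of its values are whole numbers within 0.01 (11724 of 11840 genes have such a constant). The 4 h sham table was deposited in TPM, made by the authors, per the file headers. The authors' own log2 fold changes and adjusted p-values were deposited beside these values. Most of their column names are those of DESeq2 output, but the fold change of the 4 h tables is headed logFC. Their fold changes follow morning over night in 99.67 to 100% of the genes compared in 3 tables, and in 0.198% in the 4 h sham table, which therefore runs night over morning. The authors called 2023 genes rhythmic in sham and 1163 after PHx. They called 110 genes up and 120 down for PHx at 4 h, 59 and 27 for PHx at 24 h and 236 and 204 for sham at 24 h (up is higher after morning operation), and 10 up and 40 down for sham at 4 h, where up is higher after night operation. The fold changes for PHx were fitted on 4 libraries per group, which include columns that match no labelled sample. None of these calls was used here.

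Read totals were 24.6 to 30.2 M per library in the 24 h tables, and 24.9 to 30.6 M in the counts recovered from the 4 h PHx table. The depth of the time course and of the 4 h sham table cannot be read from their values. Genes without a symbol in a table were named from the reference gene table (29 in the time course, 516 in the 4 h PHx, 630 in the 24 h PHx and 586 in the 24 h sham table).

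Time course values were tested with limma 3.58.1 in R 4.3.3 (eBayes with a trend, two-sided) on log2(value + 1) as deposited, with 1 mean per group in a fit of all 48 libraries. Genes with a value of at least 1 in at least 3 libraries were kept (12957 of 14620). The 24 h counts were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F-test), in 6 libraries for morning against night (12658 genes after PHx, 12345 in sham) and in 12 libraries for PHx against sham after night operation and for the difference of the PHx response (12056 genes). The 4 h sham table was tested with limma on log2(TPM + 1) of 11391 genes. The 4 h PHx table was tested with limma on TMM-scaled values of 8311 genes, because its signal is not scaled to depth. That departs from the planned values as deposited. P-values were adjusted with Benjamini-Hochberg within each comparison, and a call is an adjusted p under 0.05 with no fold limit. Rhythm was tested with cosine and sine terms of a fixed 24 h period on time after the operation (12005 genes in sham, 12315 after PHx), and its difference with their interactions with the operation. Amplitude is that of the fitted curve in log2. Plots and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

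The 30 gene lists were written before the data were examined and tested with limma camera at a preset correlation of 0.01, adjusted over all lists and comparisons of a family. The same test was repeated with an estimated correlation. It asks whether a list moves up or down as a whole relative to the other genes, so members that move both ways can cancel. Lists cover clock, cell cycle, immediate early, acute phase, bile acid, P450, lipid, gluconeogenesis, urea cycle, ribosome, stress and p53 genes, hepatocyte identity and zones, and markers of Kupffer cells, monocytes, neutrophils, lymphocytes, endothelium, stellate cells, cholangiocytes, erythroid and pancreatic acinar cells. Genes named in the text follow a rule set before the data were examined. It takes the 4 largest rises and 4 largest falls among called genes of the upper expression levels, the 3 members with the smallest adjusted p of each called list, the clock genes and a fixed set of genes. Genes named for the difference of rhythm lie outside it. Results of some genes are withheld and not reported here.

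Alternatives were TMM scaling of deposited values, DESeq2 1.42.0 for counts, no filter, a pseudocount of 0.1, fits of the libraries compared alone, the replicate number as a block, a fold limit of 1 log2, the library ID series as a covariate of rhythm, rhythm without 28 and 32 h, and each library left out. Replicate numbers were checked for pairing by the correlation of deviations from group means. All 3 correlations lay over 0.1 only for morning against night sham at 24 h (0.311, 0.112 and 0.425), where any pairing would rest on these data and not on the labels.

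Each step was tested on simulated data with 200 changed genes. Changes of 1 and 2 log2 were recovered in 78.1 and 97.9% of genes for PHx against sham at 12 h (12957 genes), 80.6 and 97.2% for morning against night PHx at 4 h (8311), 51.5 and 88.9% for sham at 4 h (11391), 56.4 and 94.9% for PHx at 24 h (12658), 46.2 and 92.5% for sham at 24 h (12379 in the simulated counts, filtered anew) and 26.6 and 82.1% for the difference of the PHx response (12056). Amplitudes of 0.5 and 1 were recovered in 80.0 and 98.2% for rhythm in sham, and lost amplitudes of 0.5 and 1 in 68.9 and 93.6% (12957 genes each). False calls were 3 of 178 for PHx against sham at 12 h, 9 of 188 and 6 of 146 for morning against night at 4 h (PHx and sham), 19 of 170 and 11 of 153 at 24 h, 9 of 121 for the difference of the PHx response, 11 of 191 for rhythm in sham and 10 of 175 for the difference of rhythm. For morning against night PHx at 24 h and 4 others the share of false calls was over 5%. With nothing changed at 20 h no gene was called.

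Left out were 6 columns of 4 libraries that match no labelled sample, and the night comparison of PHx with sham at 4 h with its difference from morning, whose tables are in different units. No 2 libraries were duplicates (highest correlation 0.987). Sham 4 h replicate 1 of the time course lists 3422 genes at 0, against 768 to 1414 in the other libraries, and was kept.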

Results

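The data are RNA sequencing of mouse liver after partial hepatectomy (PHx, removal of part of the liver) or a sham operation. After a morning operation, livers were taken every 4 h from 4 to 32 h. After a night operation, livers were taken at 4 and 24 h. The 60 libraries form 20 groups of 3, and the labels give 3 mice per group. The time course holds 48 libraries and 14620 genes, of which 12957 were tested. The 24 h comparison tables hold counts, with 24.6 to 30.2 M reads per library. Changes are log2 fold changes with their standard error, PHx minus sham unless said otherwise. For limma they are differences of log2(value + 1), a scale that understates the change of genes with low values. For edgeR they are fold changes of counts, which can be very large where a group has almost no counts. P-values rest on the spread between samples within groups. In the time course this spread is shared over all groups in the fit of 48 libraries. Standard errors there are therefore not those of the compared groups alone. Groups, comparisons, tests, filters and gene lists were chosen before the data were examined, except where said otherwise. A gene is said to rise or fall where its adjusted p in the named test is under 0.05, and then the values of the compared groups did not overlap in any gene named for a 3 against 3 comparison.

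The first question is which genes PHx changed at each time. From 4 to 32 h, limma called 6077, 3206, 2099, 1770, 2379, 1594, 2659 and 1998 genes, each from 3 PHx and 3 sham libraries in a fit of all 48. With the libraries of the comparison alone, the counts were 3389 at 4 h, 980 at 16 h, 1541 at 20 h and 774 at 28 h. The acute phase genes Lcn2 and Saa2 rose at all 8 times, by 6.64 to 9.41. The fatty acid synthesis genes had their lowest list medians at 16 and 20 h (-2.59 and -2.51). G1/S genes rose in 10, 4, 12, 27, 20 and 28 of 32 from 12 to 32 h. The mitosis list was first called at 24 h, with an adjusted p of 0.25 at an estimated correlation. The share of genes called higher depended on the scaling. With the values as deposited, 1208 genes were higher and 4869 lower at 4 h, against 2792 and 2427 after TMM scaling. The pairs for 8 h were 782 and 2424 against 1364 and 1505, and for 20 h 1618 and 761 against 896 and 1138. They were 1191 and 403 against 700 and 714 at 24 h, 1935 and 724 against 985 and 1146 at 28 h, and 1532 and 466 against 743 and 827 at 32 h. At 12 and 16 h the splits were 981 and 1118, and 947 and 823. The median change of all genes was -0.32, -0.15, -0.01, 0.05, 0.13, 0.10, 0.13 and 0.14 from 4 to 32 h, and from -0.02 to 0.02 after TMM scaling. Changes of single genes are to be read relative to these medians. No gene named for these times changed direction under TMM scaling.

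**Figure D1:**
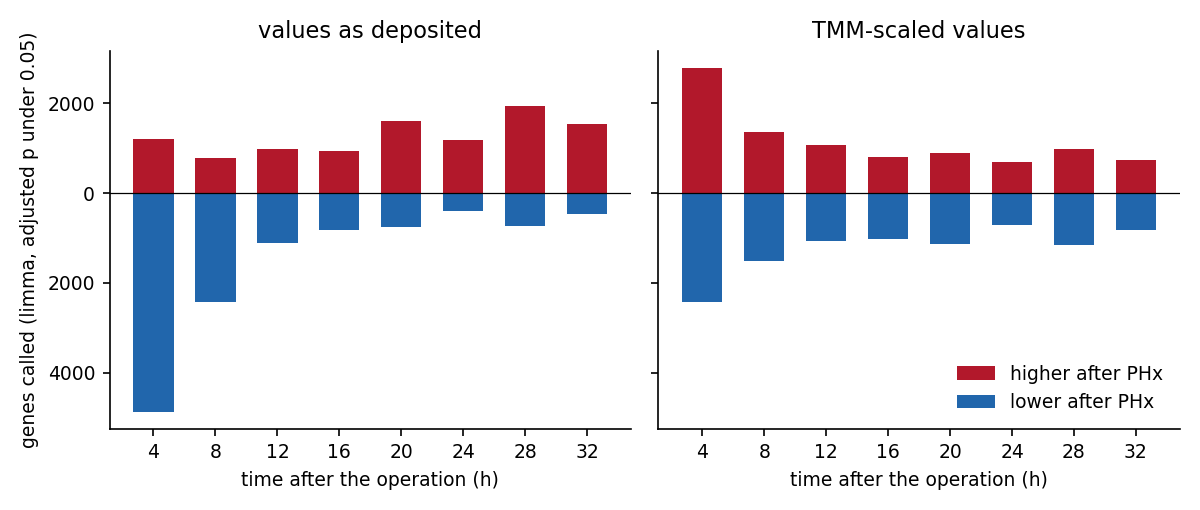
Number of genes called between PHx and sham at each time after a morning operation (3 libraries per group, limma), for the values as deposited and after TMM scaling. Bars above the line are genes higher after PHx, bars below are genes lower after PHx.

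At 4 h after PHx, acute phase genes rose: Lcn2 by 8.09 ± 0.62, Saa2 by 7.86 ± 0.63 and Saa1 by 6.78 ± 0.63. The metallothionein Mt2 rose by 8.01 ± 1.06 and the insulin-regulated Igfbp1 by 5.32 ± 0.87. Cyp7a1 (-4.27 ± 0.89), the rate-limiting enzyme of bile acid synthesis, fell, as did Angptl8 (-3.97 ± 0.79) and the lipid synthesis regulator Srebf1 (-2.23 ± 0.56). Fatty acid synthesis genes fell in 9 of 15 and cholesterol synthesis genes in 11 of 23, and none rose. Neither list was called (limma camera, adjusted p = 0.25 and 0.27). Among immediate early genes 13 of 17 rose (14 adjusted over the list alone) and none fell; Junb rose by 2.69 ± 0.39, and Myc was at 1.04 ± 0.64 (adjusted p = 0.19; 1.88 and called without sham 4 h replicate 3). Of 22 acute phase genes 19 rose and 1 fell. Gluconeogenesis and fasting genes rose in 5 of 14, with Tat at 1.86 ± 0.36. Fatty acid oxidation genes rose in 4 and fell in 1 of 21, with the lipid droplet gene Plin2 at 2.07 ± 0.51. Oxidative stress genes rose in 5 and fell in 2 of 12, with Hmox1 at 1.86 ± 0.45. Urea cycle genes rose in 4 and fell in 2 of 15; their list was called higher with a mean of 0.12 but a median of -0.10 (adjusted p = 0.55 with an estimated correlation), and Agxt rose by 1.45 ± 0.22. The periportal list was called higher with 3 rises and 2 falls of 14, a mean of 0.24 and a median of -0.01 (adjusted p = 0.36 with an estimated correlation).

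Markers of other cells also moved at 4 h. Kupffer cell and macrophage markers fell in 9 of 14 and rose in none, among them Slc40a1 (-1.99 ± 0.24), Adgre1 (-2.36 ± 0.36, and -1.49 without sham 4 h replicate 2) and Vsig4 (-0.96 ± 0.19). Such falls were not confined to them. Sinusoidal endothelium markers fell in 9 of 16 and rose in none, with a median of -0.74, a list not called (limma camera, adjusted p = 0.13). Neutrophil markers rose in 4 of 7, the decoy receptor Il1r2 among them. Pancreatic acinar genes rose in 1 of 10 (9 adjusted over the list alone). The amylase gene Amy2a5 was at 3.79 ± 1.59, with log2 10.77 in PHx 4 h replicate 3 alone, and lost its call without any 1 of the sham 4 h libraries. Its rise came from PHx 4 h replicate 3, and the gene has no value in the fit without that library. With other libraries left out the lowest change was 3.77. Clock genes fell in 9 and rose in 2 of 18, with a median of -0.86, and were not called as a list. The list test can miss lists whose members move both ways. Nfil3 rose by 1.16 ± 0.26 and Per1 by 1.01 ± 0.29, while Cry1 (-1.50 ± 0.25) and Clock (-1.38 ± 0.26) fell. Of the 10 lists called at 4 h (limma camera, preset correlation), acute phase kept its call with an estimated correlation (adjusted p = 0.0083). The others had adjusted p of 0.12 (immediate early genes), 0.16 (gluconeogenesis), 0.29 (neutrophil), 0.36 (periportal), 0.37 (oxidative stress), 0.52 (pancreatic acinar), 0.53 (fatty acid oxidation), 0.55 (urea cycle) and 0.61 (Kupffer). At 4 h the PHx and sham libraries carry IDs of different series, and for most genes named for this time the series was not examined. For Lcn2, Saa1 and Saa2 it is not the whole cause: sham at 24 h, of the same series as PHx at 4 h, had log2 means of 1.86, 5.38 and 5.83, sham at 4 h 1.28, 4.72 and 5.67, and PHx at 4 h 9.37, 11.5 and 13.53. Sham 4 h replicate 1 lists 3422 genes at 0 and matched a column labelled night best, so its label is in doubt; without it 5536 genes were called.

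At 8 h after PHx, lipid synthesis genes fell widely. Fatty acid synthesis genes fell in 14 of 15, with Acly at -3.12 ± 0.32, Fasn at -2.32 ± 0.40, Gpam at -2.38 ± 0.35 and Srebf1 at -3.13 ± 0.56. Cholesterol synthesis genes fell in 18 of 23 (20 adjusted over the list alone), with Sc5d at -2.75 ± 0.22, Insig1 at -3.16 ± 0.50 and Stard4 at -1.69 ± 0.26. Fatty acid oxidation genes rose in 11 and fell in 1 of 21, with Plin2 at 3.02 ± 0.51. Bile acid transporters fell in 6 of 10, among them the uptake carrier Slc10a1 (-1.53 ± 0.24), the export pump Abcb11 (-1.49 ± 0.26) and Abcc2 (-1.09 ± 0.20), and Cyp7a1 fell by 3.96 ± 0.89. Acute phase genes rose in 19 of 22 (20 adjusted over the list alone), with Saa2 at 9.41 ± 0.63, Lcn2 at 8.56 ± 0.62, Saa1 at 7.80 ± 0.63 and Serpina3n at 4.86 ± 0.26; Mt2 rose by 7.95 ± 1.06. Ribosome biogenesis genes rose in 9 and fell in 1 of 24 (Nop58 1.15 ± 0.25, Dkc1 -0.87 ± 0.19). Unfolded protein response genes rose in 10 and fell in 1 of 20 (Creld2 2.30 ± 0.36, Manf 1.84 ± 0.32, Hspa5 1.09 ± 0.20).

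The cyclin Ccnd1, which drives entry into the cell cycle, rose from 8 h (1.35 ± 0.29, adjusted p = 6.1e-04, limma). Hsd3b5 (-6.16 ± 1.18), Keg1 (-4.33 ± 0.71) and Upp2 (-4.03 ± 0.56) also fell at 8 h. Clock genes fell in 6 of 18 and rose in none, with Cry2 at -0.87 ± 0.18, and were not called as a list. Gluconeogenesis genes rose in 3 of 14, a list not called after TMM scaling (adjusted p = 0.080). Of the 8 lists called, acute phase kept its call with an estimated correlation (adjusted p = 6.2e-04). The others had adjusted p of 0.12 (fatty acid synthesis), 0.18 (bile acid transport, ribosome biogenesis and unfolded protein response), 0.20 (fatty acid oxidation), 0.37 (cholesterol synthesis) and 0.42 (gluconeogenesis).

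At 12 h after PHx, some replication genes rose. In the G1/S and DNA replication list 10 genes rose and 2 fell of 32 (15 and 2 adjusted over the list alone), with the helicase subunits Mcm3 (2.24 ± 0.47) and Mcm4 (1.99 ± 0.36), and Ccnd1 at 1.60 ± 0.29. Fatty acid oxidation genes rose in 13 of 21, with Acot2 at 3.03 ± 0.47, Cpt2 at 1.01 ± 0.13 and Slc25a20 at 0.97 ± 0.15; the lipid droplet gene Cidec rose by 4.78 ± 1.01. Ribosome biogenesis genes rose in 9 of 24 (Nop58 1.49 ± 0.25, Nhp2 1.12 ± 0.17) and unfolded protein response genes in 9 of 20 (Manf 2.13 ± 0.32, Hspa5 1.23 ± 0.20). In the heat shock and temperature list 4 of 13 rose, with the cold-induced Rbm3 at 1.52 ± 0.39 and the chaperone Hsp90aa1 at 1.10 ± 0.26. In the acute phase list 17 of 22 rose (Lcn2 6.67 ± 0.62, Saa2 6.64 ± 0.63, Serpina3n 3.26 ± 0.26).

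Some genes of the differentiated hepatocyte fell at 12 h. In the hepatocyte identity list 8 fell and 1 rose of 20, with Alb at -0.80 ± 0.15 (adjusted p = 3.1e-04, limma) and Apoh at -0.88 ± 0.12. Cytochrome P450 genes fell in 7 of 20 (12 adjusted over the list alone), with Cyp2a5 at -2.93 ± 0.49 and Cyp1a2 at -1.66 ± 0.45. Bile acid transporters fell in 4 of 10 (Slco1a1 -1.39 ± 0.36, Abcb11 -1.09 ± 0.26). In fatty acid synthesis 8 genes fell and 1 rose of 15 (Srebf1 -3.08 ± 0.56, Fasn -1.59 ± 0.40, Acaca -1.19 ± 0.24), and cholesterol synthesis genes fell in 3 of 23 (Nsdhl -1.51 ± 0.32, Sc5d -1.21 ± 0.22). Sinusoidal endothelium markers fell in 4 of 16. Upp2 (-4.74 ± 0.56), Hsd3b5 (-4.43 ± 1.18) and the steroid-binding Serpina6 (-3.52 ± 0.78) also fell. The count of 2099 genes was 1384 without PHx 12 h replicate 1 and 1390 without sham 12 h replicate 1. Of 12 lists called, acute phase kept its call with an estimated correlation (adjusted p = 0.0065); the others had adjusted p of 0.14 (fatty acid oxidation), 0.18 (bile acid transport, P450, unfolded protein response and hepatocyte identity), 0.20 (ribosome biogenesis), 0.26 (fatty acid synthesis), 0.32 (heat shock), 0.47 (endothelium), 0.58 (G1/S) and 0.73 (cholesterol synthesis).

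At 16 h after PHx, fatty acid synthesis genes fell in 14 of 15, with Thrsp at -4.06 ± 0.44, Fasn at -2.93 ± 0.40, Acly at -2.70 ± 0.32, Pklr at -2.69 ± 0.31 and Srebf1 at -2.62 ± 0.56. Srebf1 was at -1.47 without PHx 16 h replicate 2, and it, Nhp2 and Cyp8b1 were not called with the libraries of 16 h alone. Unfolded protein response genes rose in 11 of 20 (Creld2 3.09 ± 0.36, Hspa5 1.72 ± 0.20, Calr 1.42 ± 0.16) and ribosome biogenesis genes in 10 of 24 (16 adjusted over the list alone, Nop58 1.10 ± 0.25, Nhp2 0.76 ± 0.17). Acute phase genes rose in 19 of 22 (Saa2 8.42 ± 0.63, Lcn2 7.88 ± 0.62, Orm2 4.41 ± 0.51). Urea cycle and amino acid genes fell in 7 and rose in 1 of 15 (Prodh -1.79 ± 0.36, Gls2 -1.69 ± 0.20, Otc -0.89 ± 0.17). P450 genes fell in 9 and rose in 1 of 20 (Cyp2a4 -4.97 ± 1.00, Cyp2c37 -1.44 ± 0.34, Cyp2f2 -1.11 ± 0.27), and the hepatocyte factor Cebpa fell by 1.84 ± 0.22 in a list with 6 falls and 1 rise of 20. Bile acid synthesis genes fell in 4 of 12 (Akr1d1 -1.40 ± 0.25, Slc27a5 -0.89 ± 0.13); Cyp8b1 fell by 3.01 ± 0.80, but was at -1.63 and not called without PHx 16 h replicate 2.

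Ccnd1 rose by 1.75 ± 0.29 at 16 h (adjusted p = 5.2e-05, limma), and 4 genes rose and 1 fell of 32 in the G1/S list (8 and 1 adjusted over the list alone). The gluconeogenic Pck1 rose by 1.90 ± 0.34 and Mt2 by 4.39 ± 1.06, with oxidative stress genes rising in 4 and falling in 1 of 12. Upp2 (-5.07 ± 0.56) and Inmt (-3.88 ± 0.59) also fell. S100a9 rose by 3.04 ± 0.75, the 1 neutrophil marker called of 7 (4 adjusted over the list alone). Of the clock genes 1 of 18 fell, and of the lymphocyte markers 1 of 8, a list not called after TMM scaling (adjusted p = 0.055). The pancreatic acinar list was called higher with no gene called of 10 (adjusted p = 0.72 with an estimated correlation); Amy2a5 was at 2.90 ± 1.59 (adjusted p = 0.26), with log2 8.66 in PHx 16 h replicate 3. The count of 1770 genes was 1130 without PHx 16 h replicate 2. Of 14 lists called, acute phase (adjusted p = 0.0028), fatty acid synthesis (0.0042) and unfolded protein response (0.016) kept their calls with an estimated correlation. The others had 0.12 (P450), 0.18 (urea cycle), 0.20 (bile acid synthesis and ribosome biogenesis), 0.23 (hepatocyte identity), 0.31 (clock), 0.37 (neutrophil and lymphocyte), 0.55 (oxidative stress), 0.72 (pancreatic acinar) and 0.79 (G1/S).

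At 20 h after PHx, some metabolic genes of the hepatocyte fell. In the fatty acid synthesis list 13 of 15 fell (15 adjusted over the list alone), with Thrsp at -4.96 ± 0.44, Pklr at -3.27 ± 0.31, Fasn at -2.82 ± 0.40 and Acacb at -2.75 ± 0.31. P450 genes fell in 11 of 20 (Cyp2c29 -2.08 ± 0.47, Cyp2c70 -1.57 ± 0.31, Cyp2f2 -1.51 ± 0.27). Bile acid synthesis genes fell in 5 of 12 (Cyp8b1 -4.95 ± 0.80, Cyp7a1 -3.76 ± 0.89, Slc27a5 -1.17 ± 0.13, Cyp27a1 -1.14 ± 0.18). Urea cycle genes fell in 5 and rose in 1 of 15 (Gls2 -1.54 ± 0.20, Otc -1.22 ± 0.17). Hepatocyte identity genes fell in 7 and rose in 2 of 20 (Cebpa -1.42 ± 0.22, Ttr -0.99 ± 0.17). Periportal markers fell in 4 and rose in 2 of 14 (Sds -2.14 ± 0.35), and pericentral markers fell in 2 of 14. Upp2 fell by 5.04 ± 0.56 and Hamp2 by 4.59 ± 0.66.

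Some stress and cell cycle genes rose at 20 h. Acute phase genes rose in 19 of 22 (Lcn2 8.58 ± 0.62, Saa2 8.39 ± 0.63), immediate early genes in 10 of 17 (Junb 2.03 ± 0.39, Atf3 2.01 ± 0.39), unfolded protein response genes in 10 of 20 (Sdf2l1 2.16 ± 0.36, Calr 1.15 ± 0.16) and oxidative stress genes in 7 of 12 (Mt2 5.52 ± 1.06, Mt1 4.20 ± 0.85, Srxn1 1.70 ± 0.37). Ribosome biogenesis genes rose in 5 of 24 (Nhp2 1.12 ± 0.17), a list not called after TMM scaling (adjusted p = 0.070). Ccnd1 rose by 2.44 ± 0.29, and 12 genes rose and 2 fell of 32 in the G1/S list. In that list Ccne1 (2.02 ± 0.50), the ligase Lig1 (2.01 ± 0.48) and Pcna (1.02 ± 0.32) rested on PHx 20 h replicate 2: without it they were at 1.40, 1.22 and 0.45 and not called. Pcna was also not called without sham 20 h replicate 1 (0.95) or 3 (0.99). With the libraries of 20 h alone, Ccne1, Lig1, Pcna and Cyp7a1 were not called. The mitosis marker Mki67 was at 0.40 ± 0.64 (adjusted p = 0.73) and at -0.84 without PHx 20 h replicate 2. Clock genes fell in 4 and rose in 1 of 18. Among markers of other cells, the lymphocyte Cd4 (-0.78 ± 0.17) and the erythroid Car1 (-1.65 ± 0.26) fell, with 1 fall of 8, and 2 falls of 7 and an erythroid median of 0.05 and mean of -0.39; endothelial markers fell in 3 of 16. The count of 2379 genes was 1566 without sham 20 h replicate 3 and 1567 without PHx 20 h replicate 3. Of 17 lists called, fatty acid synthesis (adjusted p = 0.0042) and acute phase (0.0050) kept their calls with an estimated correlation. The others had 0.071 (bile acid synthesis), 0.11 (P450), 0.18 (unfolded protein response, hepatocyte identity and lymphocyte), 0.20 (clock), 0.27 (urea cycle), 0.31 (immediate early and periportal), 0.32 (oxidative stress), 0.37 (erythroid), 0.52 (pericentral), 0.57 (endothelium), 0.58 (ribosome biogenesis) and 0.65 (G1/S).

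**Figure D2:**
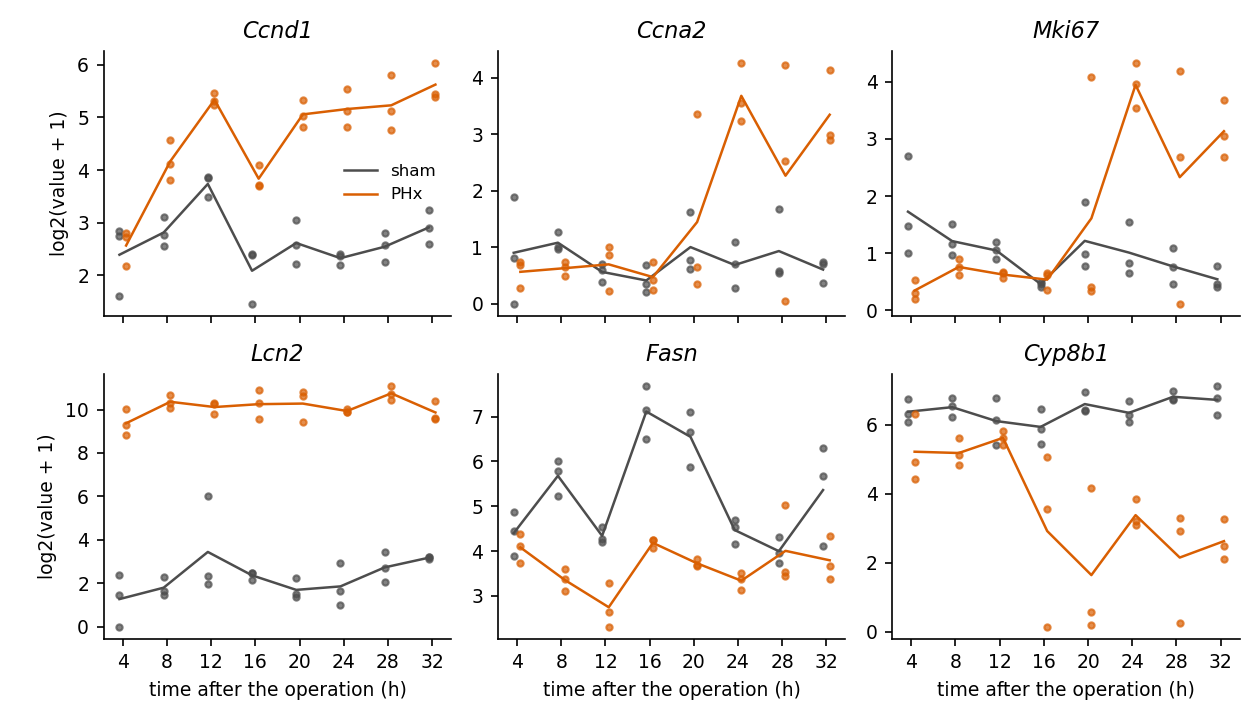
Values of 6 genes in each library of the morning time course, sham and PHx, as log2(value + 1). Lines join group means (3 libraries each). Ccnd1, Ccna2 and Mki67 belong to the cell cycle, Lcn2 to the acute phase, Fasn to fatty acid synthesis and Cyp8b1 to bile acid synthesis.

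At 24 h after PHx, many cell cycle genes rose. In the G1/S list 27 of 32 genes rose (29 adjusted over the list alone) and none fell, with Ccnd1 at 2.83 ± 0.29 (adjusted p = 1.7e-08, limma), Ccne1 at 2.84 ± 0.50, Lig1 at 2.85 ± 0.48 and Pcna at 1.58 ± 0.32. In the G2/M and mitosis list 20 of 24 rose (23 adjusted over the list alone), with Ccna2 at 2.99 ± 0.62, Mki67 at 2.94 ± 0.64, Cenpe at 1.76 ± 0.30 and Cenpf at 1.57 ± 0.25. Cdk1 rose by 3.02 ± 0.80, but was at 2.76 and not called without sham 24 h replicate 2, and Ccnb1 was at 1.79 ± 0.62 (adjusted p = 0.052). Ribosome biogenesis genes rose in 12 of 24 (17 adjusted over the list alone, Nop58 1.30 ± 0.25, Nop56 1.16 ± 0.24). Of the acute phase genes 18 of 22 rose (Saa2 8.91 ± 0.63, Lcn2 8.07 ± 0.62), immediate early genes in 4 of 17 (Jun 2.01 ± 0.46, Atf3 1.77 ± 0.39) and oxidative stress genes in 5 of 12 (Mt2 6.43 ± 1.06).

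Some lipid, bile acid and amino acid genes fell at 24 h. The fatty acid synthesis list had 7 falls of 15 (Thrsp -3.79 ± 0.44, Scd1 -2.09 ± 0.32, Acacb -1.71 ± 0.31), cholesterol synthesis genes in 2 of 23 (1 adjusted over the list alone, Sc5d -1.03 ± 0.22), bile acid synthesis genes in 5 of 12 (Cyp8b1 -2.96 ± 0.80, Cyp27a1 -1.03 ± 0.18, Baat -0.84 ± 0.18, Slc27a5 -0.57 ± 0.13) and urea cycle genes in 3 of 15 (Tdo2 -1.43 ± 0.23, Gls2 -1.11 ± 0.20, Otc -0.93 ± 0.17). Car3 (-3.36 ± 0.61) and Upp2 (-3.21 ± 0.56) also fell. Kupffer and macrophage markers rose in 2 of 14, with Marco at 3.81 ± 0.70. Lymphocyte markers fell in 1 of 8, erythroid in 2 of 7 (Car1 -1.44 ± 0.26), clock genes in 1 of 18, and the pancreatic acinar list was called lower with no gene called; these last 4 lists were not called after TMM scaling (adjusted p = 0.14, 0.091, 0.096 and 0.19). The mean of the acinar genes was log2 4.24 in sham 24 h replicate 3 and at most 0.71 in the other 24 h libraries of the time course. Slc27a5 was not called with the libraries of 24 h alone, Cyp8b1 not with a pseudocount of 0.1. The count of 1594 genes was 1011 without sham 24 h replicate 2 and 1023 without PHx 24 h replicate 1. Of 15 lists called, acute phase kept its call with an estimated correlation (adjusted p = 0.0042). The others had 0.071 (fatty acid synthesis), 0.079 (bile acid synthesis), 0.18 (ribosome biogenesis), 0.20 (G1/S), 0.21 (urea cycle), 0.25 (G2/M), 0.31 (oxidative stress), 0.32 (clock), 0.36 (lymphocyte), 0.42 (immediate early and erythroid), 0.63 (Kupffer), 0.64 (cholesterol synthesis) and 0.70 (pancreatic acinar).

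At 28 h after PHx, G1/S genes rose in 20 and fell in 1 of 32 (25 and 1 adjusted over the list alone), with Ccnd1 at 2.69 ± 0.29, Lig1 at 2.62 ± 0.48, Ccne1 at 2.56 ± 0.50 and Pcna at 1.56 ± 0.32. Mitosis genes rose in 5 of 24 (14 adjusted over the list alone). Mki67 was at 1.57 ± 0.64 (adjusted p = 0.080) and Cdk1 at 1.62 ± 0.80 (0.15); without PHx 28 h replicate 2 they were at 2.68 and 3.30 and called. Immediate early genes rose in 13 of 17 (Atf3 2.14 ± 0.39, Nr4a1 1.75 ± 0.44), acute phase genes in 15 of 22 (Saa2 8.03 ± 0.63, Lcn2 8.01 ± 0.62), oxidative stress genes in 6 of 12 (Srxn1 1.87 ± 0.37) and ribosome biogenesis genes in 9 of 24 (Nhp2 1.05 ± 0.17). Cdkn1a (2.24 ± 0.59) and Pck1 (1.51 ± 0.34) also rose.

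Bile acid synthesis genes fell in 8 of 12 at 28 h (10 adjusted over the list alone), with Cyp8b1 at -4.65 ± 0.80, Cyp27a1 at -1.55 ± 0.18 and Slc27a5 at -1.27 ± 0.13. P450 genes fell in 12 and rose in 1 of 20 (Cyp2f2 -2.06 ± 0.27, Cyp2c70 -1.66 ± 0.31, Cyp2e1 -1.54 ± 0.33) and urea cycle genes fell in 7 of 15 (Tdo2 -1.53 ± 0.23, Otc -1.47 ± 0.17, Gls2 -1.02 ± 0.20). Fatty acid synthesis genes fell in 4 of 15 (Thrsp -2.75 ± 0.44, Scd1 -2.08 ± 0.32, Pklr -1.14 ± 0.31), hepatocyte identity genes in 5 with 2 rises of 20, and pericentral markers in 2 of 14. Car3 fell by 4.57 ± 0.61 and Inmt by 4.16 ± 0.59. Without PHx 28 h replicate 2, Cyp2c70 was at -1.06 and Cyp2f2 at -1.36. With the libraries of 28 h alone, Lig1, Pcna, Cyp2f2, Cyp2c70, Cyp2e1 and Gls2 were not called. Lymphocyte markers fell in 2 of 8 (Cd4 -0.75 ± 0.17) and erythroid in 3 of 7 (Car1 -1.63 ± 0.26), with an erythroid median of 0.04 and mean of -0.46. Of 14 lists called, bile acid synthesis kept its call with an estimated correlation (adjusted p = 0.0079). The others had 0.056 (acute phase), 0.079 (P450), 0.14 (lymphocyte), 0.18 (hepatocyte identity), 0.21 (urea cycle), 0.26 (immediate early), 0.31 (erythroid), 0.40 (oxidative stress), 0.42 (ribosome biogenesis), 0.47 (G1/S), 0.54 (fatty acid synthesis and pericentral) and 0.63 (G2/M).

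At 32 h after PHx, many cell cycle genes rose. In the G1/S list 28 of 32 rose (30 adjusted over the list alone), with Mcm3 at 3.37 ± 0.47, Mcm4 at 2.82 ± 0.36, Ccne1 at 2.73 ± 0.50, Ccnd1 at 2.72 ± 0.29 and Pcna at 1.71 ± 0.32. In the G2/M list 23 of 24 rose (24 adjusted over the list alone), with Prc1 at 3.90 ± 0.78, Cdk1 at 3.17 ± 0.80, Ccnb1 at 3.12 ± 0.62 (adjusted p = 6.1e-04, limma), Ccna2 at 2.74 ± 0.62 and Plk1 at 2.70 ± 0.55. Acute phase genes rose in 17 of 22 (Saa2 7.70 ± 0.63, Lcn2 6.68 ± 0.62, Orm2 3.90 ± 0.51), immediate early genes in 3 of 17 (Fosl2 1.08 ± 0.17) and ribosome biogenesis genes in 5 of 24, a list not called after TMM scaling (adjusted p = 0.091). Clock genes rose in 1 (Nfil3, 1.19 ± 0.26) and fell in 1 of 18. Fatty acid synthesis genes fell in 4 of 15 (Thrsp -3.84 ± 0.44, Scd1 -2.10 ± 0.32, Pklr -1.53 ± 0.31), and cholesterol synthesis genes in 2 of 23 (0 adjusted over the list alone).

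Bile acid synthesis genes fell in 5 of 12 at 32 h (Cyp8b1 -4.09 ± 0.80, Slc27a5 -1.19 ± 0.13, Cyp27a1 -1.13 ± 0.18), bile acid transporters in 2 of 10 (Slc10a1 -1.20 ± 0.24, not called as a list after TMM scaling, adjusted p = 0.058) and urea cycle genes in 4 with 2 rises of 15 (Tdo2 -1.18 ± 0.23, Otc -1.01 ± 0.17). P450 genes fell in 3 and rose in 1 of 20 (Cyp2a5 -2.11 ± 0.49, Cyp2f2 -1.49 ± 0.27, Cyp2d9 -1.22 ± 0.24), hepatocyte identity genes fell in 3 and rose in 1 of 20 (Apoh -0.55 ± 0.12), and periportal markers fell in 3 and rose in 1 of 14. Hamp2 (-4.26 ± 0.66) and Car3 (-3.14 ± 0.61) also fell. Lymphocyte markers fell in 4 of 8 (Cd4 -0.87 ± 0.17) and erythroid in 3 of 7 (Car1 -1.51 ± 0.26, Klf1 -1.14 ± 0.23). The count of 1998 genes was 1116 without PHx 32 h replicate 1 and 1326 without sham 32 h replicate 3. Of 15 lists called, acute phase and bile acid synthesis (both adjusted p = 0.021) and lymphocyte (0.031) kept their calls with an estimated correlation. The others had 0.18 (G1/S, bile acid transport, P450, fatty acid synthesis, hepatocyte identity and erythroid), 0.20 (urea cycle), 0.25 (G2/M), 0.28 (periportal), 0.42 (cholesterol synthesis), 0.57 (ribosome biogenesis) and 0.58 (immediate early). The cholangiocyte list was not called in any comparison.

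**Figure D3:**
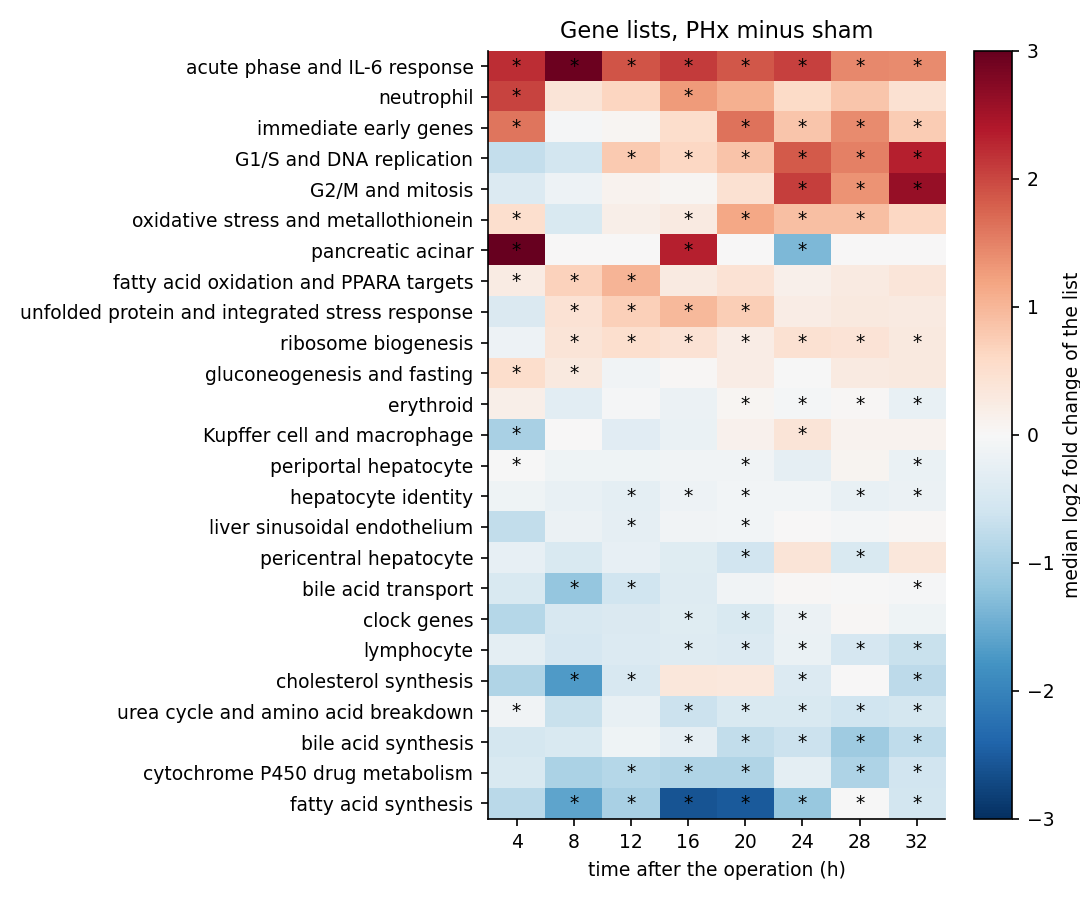
Median log2 fold change, PHx minus sham, of the gene lists called at 2 or more times after a morning operation (3 libraries per group). An asterisk marks an adjusted p under 0.05 in limma camera with a preset correlation; the calls kept with an estimated correlation are fewer. The median of all genes was -0.32 at 4 h.

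The second question is which genes follow a 24 h rhythm after a sham operation and after PHx. A change with time after the operation that does not repeat each day can also pass the test of rhythm. Calls, amplitudes and peaks therefore describe the fitted curve. In sham, 3356 of 12005 genes were called rhythmic (limma, 24 libraries), 16 of 18 clock genes among them. Genes with large amplitudes were the steroid hydroxylase Cyp2a4 (2.82 ± 0.36, peak 16.3 h after the operation), Mup13 (2.29 ± 0.33), Elovl3 (2.22 ± 0.19, peak 2.1 h) and the clock output gene Dbp (2.21 ± 0.48, peak 11.5 h). Arntl peaked at 0.49 h (amplitude 1.24 ± 0.25), Ciart at 13.4 h (1.79 ± 0.29) and Per2 at 14.5 h (0.88 ± 0.13). Rhythmic genes included 12 of 15 for fatty acid synthesis (Thrsp 1.84 ± 0.28), P450 and unfolded protein response genes in 10 of 20 and 10 of 19, sinusoidal endothelium markers in 9 of 16, acute phase genes in 9 of 22 and bile acid synthesis genes in 7 of 12. After PHx, 1020 of 12315 genes were called, with 9 of 18 clock genes (15 adjusted over the list alone). Mup13 (2.26 ± 0.48), Dbp (1.81 ± 0.45, peak 10.5 h), Gsta1 (1.71 ± 0.37), Elovl3 (1.71 ± 0.25, peak 2.6 h), Arntl (1.06 ± 0.19, peak 23.8 h) and Ciart (1.10 ± 0.29) were among them. Rhythm was then called in 2 of 15 fatty acid synthesis genes, sinusoidal endothelium markers in 0 of 16 by limma, bile acid synthesis genes in 1 of 12, and cholesterol synthesis genes in 7 of 23 (15 adjusted over the list alone) against 8 of 23 in sham. Of 11651 genes tested in both, 3317 were called in sham, 991 after PHx and 432 in both, where independent lists would share 282.1.

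These counts moved with the libraries used. In sham 441 genes were called with the library ID series as a covariate, where Elovl3, Dbp, Arntl and Ciart kept their calls and Cyp2a4, Mup13 and Thrsp did not. After PHx 1868 genes were called with that covariate and 3347 without 28 and 32 h. Of the 1020 genes called after PHx in the main fit, these held 442 and 852. Without all libraries numbered 1, 2 or 3, 815 to 1066 genes were called in sham and 30 to 138 after PHx; Dbp and Arntl lost their call in both without the libraries numbered 3 (amplitudes 2.14 and 1.14 in sham, 1.74 and 0.95 after PHx).

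A rhythm called in one group alone is no difference between groups, so the difference itself was tested, and 19 of 12957 genes were called (limma, 48 libraries). They were singled out after their values were seen. The test takes cosine and sine terms together, so a shift of the peak alone can pass it, and amplitude alone was not tested. The adjusted p-values beside amplitudes below are those of this joint test. The unfolded protein response genes Hspa5, Creld2 and Manf peaked 1.7, 2.6 and 2.0 h after sham operation and 16.9, 14.8 and 15.6 h after PHx (adjusted p = 0.0041, 0.010 and 0.019). Hsp90b1 had an amplitude of 0.19 in sham and 0.59 after PHx (adjusted p = 0.0039), while Sdf2l1 had 1.02 and 0.54 (0.036) and Pdia4 0.64 and 0.40 (0.043). The cholesterol synthesis genes Hmgcs1 (0.33 and 1.31; 0.036), Mvk (0.53 and 0.80; 0.020) and Msmo1 (0.53 and 1.04; 0.047) had a larger amplitude after PHx. The glucose transporter Slc2a4 went from 0.73 in sham to 0.07 (adjusted p = 0.036). Bhlhe40, rhythmic in sham (0.83 ± 0.13) and at 0.07 ± 0.14 after PHx, did not pass (adjusted p = 0.10). The count was 2371 without 28 and 32 h, 105 with the library ID series as a covariate, 46 with TMM scaling, where Hmgcs1 and Msmo1 lost their calls, and 12 with a pseudocount of 0.1. Without the libraries numbered 1, 2 or 3 it was 1, 7 and 0, and without sham 4 h replicate 1 it was 32.

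**Figure D4:**
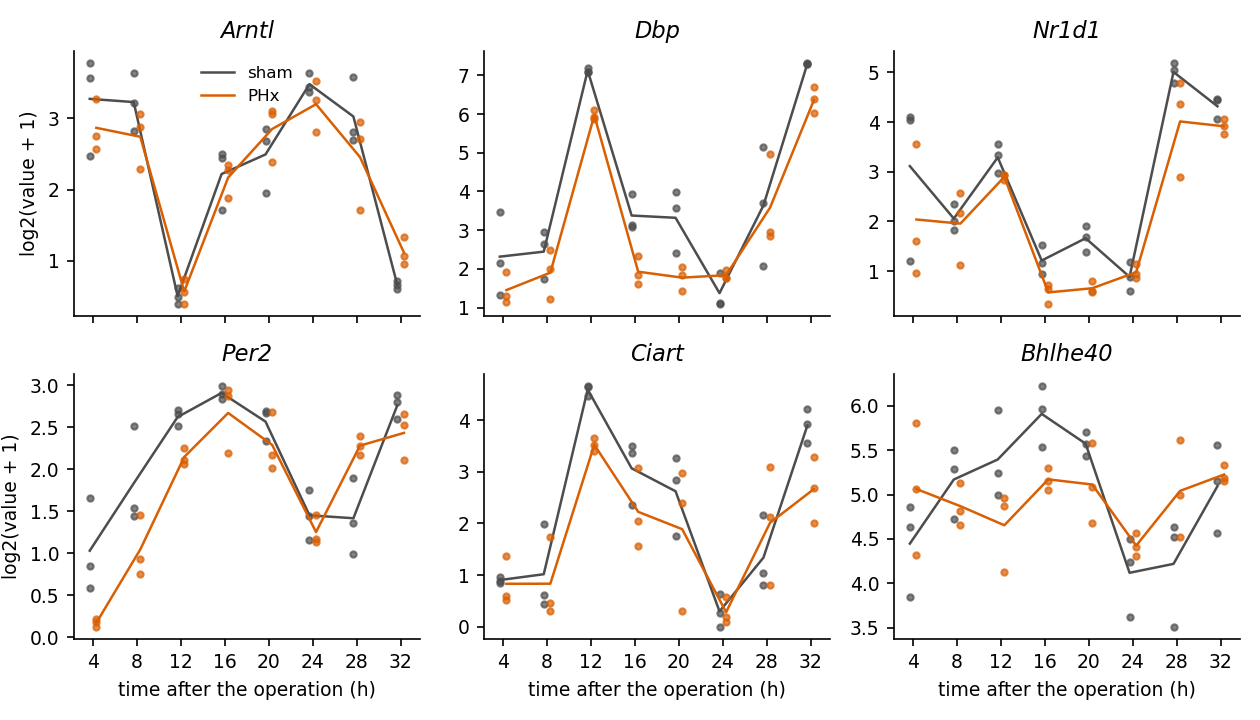
Clock genes in each library of the morning time course, sham and PHx, as log2(value + 1). Lines join group means (3 libraries each). Libraries at 4, 8 to 20, 24, and 28 and 32 h carry IDs of different series.

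The next question is whether sham livers differ a day apart at the same clock time. From 8 to 32 h after sham operation, 1762 genes changed (666 higher, 1096 lower; limma). Dbp rose by 4.86 ± 0.53 (adjusted p = 6.7e-08), Ciart by 2.88 ± 0.54, Nr1d1 by 2.26 ± 0.51 and Per3 by 1.13 ± 0.23, while Arntl (-2.56 ± 0.31), Nfil3 (-2.02 ± 0.26) and Clock (-1.38 ± 0.26) fell. Immediate early genes fell in 10 of 17 (Jun -2.93 ± 0.46, Dusp1 -2.26 ± 0.41, Zfp36 -2.05 ± 0.36) and p53 targets in 4 of 12 (Cdkn1a -2.58 ± 0.59, Trp53inp1 -1.88 ± 0.24). Of the fatty acid synthesis genes 5 of 15 fell (Scd1 -2.28 ± 0.32, Me1 -1.82 ± 0.33), acute phase genes rose in 3 of 22 (Lbp 1.22 ± 0.28, Serpina3n 1.00 ± 0.26) and Kupffer markers in 4 of 14 (Cd68 1.52 ± 0.29). Cyp3a11 fell by 2.79 ± 0.32. From 4 to 28 h, 2647 genes changed (1195 higher, 1452 lower). Hepatocyte identity genes rose in 11 and fell in 1 of 20 (Rbp4 0.64 ± 0.12, Serpina1a 0.52 ± 0.10, Apob -1.02 ± 0.17), pericentral markers rose in 2 of 14 (Cyp27a1 0.92 ± 0.18) and fatty acid synthesis genes fell in 4 of 15 (Scd1 -2.33 ± 0.32, Me1 -1.45 ± 0.33). Scand1 rose by 3.33 ± 0.34; Cyp3a11 (-3.06 ± 0.32) and Rora (-1.13 ± 0.24) fell. Nr1d1 rose by 1.90 ± 0.51, but was at 0.94 and not called without sham 4 h replicate 3. The count for 4 to 28 h was 1706 without sham 28 h replicate 1 and 2050 without sham 4 h replicate 1, whose label is in doubt, and that for 8 to 32 h 1167 and 1174 without sham 32 h replicate 2 and 3. With an estimated correlation none of the 3 and 5 lists called was called (adjusted p from 0.63 to 0.97). Library ID series differ in both, so time and series cannot be told apart gene by gene.

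The last question is whether expression at a fixed time after the operation differed between morning and night operation. At such a fixed time, livers of the morning and night groups were taken at different times of day. Time of operation and time of day at collection therefore cannot be told apart, also for the difference of the PHx response. At 24 h after sham operation 661 genes differed (339 higher and 322 lower after the morning operation; edgeR, 3 against 3). Clock genes differed in 17 of 19, with 5 higher and 12 lower in the morning group. Npas2 (5.80 ± 0.34), Arntl (4.73 ± 0.32), Nfil3 (2.56 ± 0.22), Clock (1.81 ± 0.21) and Cry1 (1.63 ± 0.20) were higher, and Ciart (-7.93 ± 0.63), Dbp (-6.64 ± 0.46), Nr1d2 (-3.55 ± 0.25), Per3 (-3.15 ± 0.33), Nr1d1 (-2.80 ± 0.28), Tef (-2.52 ± 0.15) and Per1 (-2.48 ± 0.23) lower. Rgs16 (-8.54 ± 0.42, adjusted p = 2.8e-06) and Usp2 (-3.75 ± 0.38) were also lower and Elovl3 (4.68 ± 0.20), Cdkn1a (3.85 ± 0.35) and Tubb2a (3.50 ± 0.29) higher. Ciart, Dbp and Rgs16 were near 0 in the morning group, with mean log2(CPM + 1) of 0.06, 0.46 and 0.48. In the night group these means were 3.69, 5.43 and 7.14. Unfolded protein response genes were higher in 9 and lower in 1 of 20 (Sdf2l1 2.39 ± 0.33, Hyou1 1.65 ± 0.23, Pdia4 1.45 ± 0.18), cholesterol synthesis genes higher in 3 of 23 and gluconeogenesis genes lower in 4 of 14 (Slc37a4 -1.48 ± 0.16). Bile acid transport, pericentral and Kupffer lists were called lower with 1 gene called in each. None of the 7 lists called was called with an estimated correlation. Of the cell cycle regulators Wee1 (-2.76 ± 0.25) and Ccne1 (-2.33 ± 0.32) were lower. The count fell to 215 without morning sham 24 h replicate 1 and rose to 1022 without night sham 24 h replicate 3, in which the mean of the pancreatic acinar genes was log2 9.43 against 0.47 to 4.07 in the other 5 libraries. DESeq2 called 1047 genes. The clock genes named here kept their calls with each library left out.

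At 24 h after PHx 42 genes differed (32 higher and 10 lower after the morning operation; edgeR), against 252 by DESeq2 and 14 with the replicate number as a block. Npas2 (3.94 ± 0.36) was higher and Nr1d2 (-2.63 ± 0.25) and Tef (-1.99 ± 0.14) lower, with Ndrg1 (2.82 ± 0.27) and Ces1d (1.88 ± 0.21) higher. Clock genes differed in 8 of 18, 2 higher and 6 lower (13 adjusted over the list alone, 4 and 9). Ciart (-4.46 ± 0.58), Per3 (-2.72 ± 0.40), Per1 (-1.84 ± 0.28), Per2 (-1.40 ± 0.23) and Cry1 (1.27 ± 0.20) were called, but not without morning PHx 24 h replicate 1 or 2 (Ciart at -4.11 without replicate 1). In the mitosis list 6 of 23 genes were higher (22 adjusted over the list alone), with Cenpf at 2.43 ± 0.27, Plk1 at 2.25 ± 0.26 and Cenpe at 1.72 ± 0.23; Plk1 and Cenpe were not called without morning PHx 24 h replicate 2 (2.24 and 1.69). Mki67 was at 1.86 ± 0.52 (adjusted p = 0.23; 2.89 and called without night PHx 24 h replicate 2). Elovl3 was at 2.16 ± 0.33, and 1.99 and not called without morning PHx 24 h replicate 2. Of 13 lists called, 9 were higher and 4 lower, and with an estimated correlation none was called. Besides G2/M and clock, no member was called in any, with medians of 0.49 (P450), 0.39 (immediate early), 0.37 (cholesterol synthesis), 0.33 (fatty acid synthesis), 0.26 (acute phase), 0.23 (unfolded protein response), 0.21 (stellate cell), 0.15 (p53 targets), -0.20 (ribosome biogenesis), -0.21 (G1/S) and -0.31 (urea cycle). The count ranged from 9 without morning PHx 24 h replicate 2 to 193 without night PHx 24 h replicate 2.

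**Figure D5:**
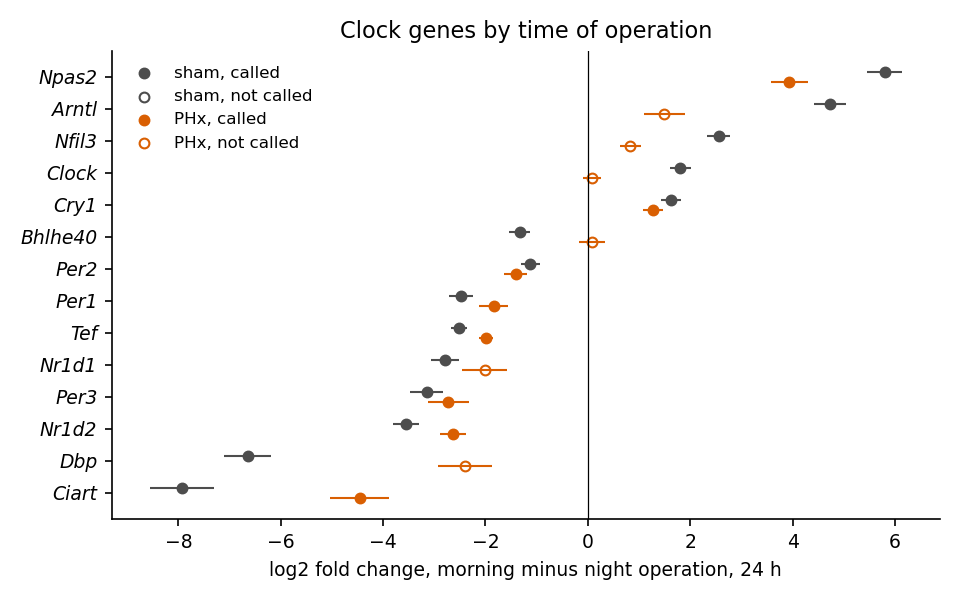
Log2 fold change of clock genes between morning and night operation at 24 h, after sham operation and after PHx (3 against 3 libraries each, edgeR). Bars are standard errors.

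At 4 h after PHx 78 genes differed between morning and night operation (33 higher, 45 lower; limma on TMM-scaled values), and 21 with the replicate number as a block. Clock genes were lower in 5 of 15 (Tef -1.48 ± 0.18, Cry1 -1.29 ± 0.16, Per2 -1.24 ± 0.13, Ciart -1.10 ± 0.18). Fatty acid oxidation genes were lower in 3 of 20 (Acot2 -2.10 ± 0.31, Acot1 -1.48 ± 0.18) and fatty acid synthesis genes in 2 of 15 (Fads2 -1.75 ± 0.21, Pklr -1.20 ± 0.13). G0s2 (-2.55 ± 0.31) and Inhbe (-2.31 ± 0.23) were lower, and Elovl3 (2.21 ± 0.35), Tubb6 (2.09 ± 0.26), Tymp (2.06 ± 0.31) and Srxn1 (1.49 ± 0.19, adjusted p = 0.024) higher. Of the genes named here, Cry1, Ciart, Acot2, G0s2, Elovl3, Tubb6, Tymp and Srxn1 lost their calls in an alternative fit that kept all libraries. Immediate early, oxidative stress and neutrophil lists were called higher with 1, 1 and 0 genes called, and P450 and pericentral lists lower with 0. None of the 8 lists called was called with an estimated correlation. The counts are fragile: 0 to 48 genes were called with 1 library left out (0 without night PHx 4 h replicate 1 or 2, 48 without morning PHx 4 h replicate 1). By the labels, night PHx 4 h replicate 3 was sequenced on another flow cell than the other libraries compared. With the values as deposited, 32 genes were higher and 239 lower, with a median of all genes of -0.18.

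At 4 h after sham operation no gene was called between morning and night operation by limma, with 667 of 11391 genes at an unadjusted p under 0.05; with TMM scaling there were 0 calls and 596 such genes. Arntl was at 1.51 ± 0.56 (adjusted p = 0.84), Dbp at -1.10 ± 0.65 (0.86), Srebf1 at -1.12 ± 0.46 (0.84), Hsp90ab1 at 0.85 ± 0.13 (0.71) and the macrophage gene Cd68 at 1.78 ± 0.49 (0.84). The column labelled night 3 in this table was the best match of time course sham 4 h replicate 1 (correlation 0.35, next 0.09), and the column labelled morning 1 that of replicate 3 (0.36, next 0.10), so labels of this table or of the time course sham 4 h libraries are in doubt. Without morning sham 4 h replicate 2 there were 2 calls, and without night sham 4 h replicate 2 there was 1. Camera called 14 lists with medians from -0.21 (fatty acid synthesis) to 0.93 (monocyte), none of them with a gene called; the others were G2/M (0.73), acute phase (0.53), unfolded protein response (0.69), heat shock (0.35), Kupffer (0.74), endothelium (0.26), stellate cell (0.40), cholesterol synthesis (-0.20), pericentral (-0.20), fatty acid oxidation (-0.10), ribosome biogenesis (-0.10) and oxidative stress (-0.07). In the 4 morning against night comparisons no list was called with an estimated correlation (adjusted p from 0.58 to 0.71).

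After a night operation, PHx changed 2803 genes at 24 h against sham (1435 higher, 1368 lower; edgeR, 12 libraries in the fit). G1/S genes rose in 26 and fell in 1 of 29 (Mcm2 3.80 ± 0.27, Mcm6 3.65 ± 0.26, E2f1 2.73 ± 0.19, Ccnd1 2.63 ± 0.30) and G2/M genes rose in 14 of 16 (Tpx2 3.66 ± 0.46, Ccna2 3.15 ± 0.69, Top2a 2.91 ± 0.39, Mki67 2.61 ± 0.58). Acute phase genes rose in 20 and fell in 1 of 22 (Lcn2 8.47 ± 0.58, Saa2 8.09 ± 0.43, Saa1 6.19 ± 0.55, Apcs 3.23 ± 0.22), and Cdkn1a rose by 4.67 ± 0.32. Ribosome biogenesis genes rose in 11 of 24 (Nop58 1.58 ± 0.20), and unfolded protein response genes rose in 9 and fell in 3 of 19 (Sdf2l1 2.67 ± 0.32, Manf 1.87 ± 0.28). Fatty acid synthesis genes fell in 13 of 15 (Thrsp -4.50 ± 0.56, Pklr -3.93 ± 0.44, Fasn -3.24 ± 0.43), P450 genes in 13 of 19 (Cyp2f2 -1.98 ± 0.25), cholesterol synthesis genes in 5 of 23, hepatocyte identity genes in 8 of 20, bile acid synthesis genes in 4 with 1 rise of 11 (Cyp8b1 -3.52 ± 0.69, Cyp27a1 -1.30 ± 0.25) and bile acid transporters in 5 with 1 rise of 9 (Slco1a1 -2.12 ± 0.38, Slc10a1 -1.89 ± 0.24). Clock genes changed in 14 of 19: Arntl (2.83 ± 0.45) and Clock (1.56 ± 0.21) rose and Dbp (-3.58 ± 0.46), Per3 (-1.92 ± 0.35), Ciart (-1.86 ± 0.44) and Tef (-1.32 ± 0.14) fell. Upp2 (-4.53 ± 0.77) and Car3 (-3.97 ± 0.59) also fell. The pancreatic gene Cela1 fell by 6.73 ± 1.52 (adjusted p = 0.0051), but was at -1.25 and not called without night sham 24 h replicate 3, where its log2(CPM + 1) was 11.07. Without night PHx 24 h replicate 2, Mki67 was at 1.57 and Cyp8b1 at -5.60. None of the 12 lists was called with an estimated correlation (adjusted p from 0.21 to 0.58).

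Whether the response to PHx at 24 h differs between morning and night operation was tested as an interaction, and 59 genes were called (25 higher, 34 lower for morning minus night; edgeR), against 243 by DESeq2. Dbp was at 4.25 ± 0.77, Slc25a47 at 2.22 ± 0.36, Ccne1 at 2.13 ± 0.38, the glycogen synthase Gys2 at 2.08 ± 0.22 (adjusted p = 0.0011) and the kinase Wee1 at 1.97 ± 0.39. Cdkn1a was at -2.99 ± 0.40 (adjusted p = 0.0064), Tubb2a at -2.88 ± 0.46, Sdf2l1 at -2.53 ± 0.42, Elovl3 at -2.50 ± 0.41, Clock at -1.71 ± 0.28 and Nfil3 at -1.71 ± 0.31. For Cdkn1a, log2(CPM + 1) was 4.86 after morning PHx, 3.26 after morning sham, 4.06 after night PHx and 0.69 after night sham, and the difference between morning and night was larger in sham than after PHx. Dbp lost its call in several fits with a library left out, among them that without morning sham 24 h replicate 1 (3.81). Calls were also lost for Ccne1 and Wee1 without morning PHx 24 h replicate 3 (1.90 and 1.70), Nfil3 without night sham 24 h replicate 1 (-1.53), Sdf2l1 without morning PHx 24 h replicate 1 (-2.43) and Clock without morning PHx 24 h replicate 2 (-1.64). The count ranged from 26 without morning PHx 24 h replicate 1 to 130 without night PHx 24 h replicate 2. Camera called 9 lists, with medians of 1.16 (G2/M, no gene called), 0.91 (fatty acid synthesis), 0.57 (P450), 0.52 (pericentral), 0.50 (bile acid transport), 0.38 (acute phase), 0.29 (endothelium, not called without TMM, adjusted p = 0.060), 0.19 (immediate early) and -0.22 (unfolded protein response), none with an estimated correlation (adjusted p from 0.21 to 0.59). The same comparison at 4 h was not made, since the 4 h PHx and 4 h sham tables are in different units.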

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

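All tests of this part were chosen after the results were seen, except the regroupings of the samples. Items singled out here are those where a response was called to differ between groups of animals. The difference of the PHx response between morning and night operation at 24 h had 59 genes. Its named genes were Dbp (4.25), Slc25a47 (2.22), Ccne1 (2.13), Gys2 (2.08), Wee1 (1.97), Cdkn1a (-2.99), Tubb2a (-2.88), Sdf2l1 (-2.53), Elovl3 (-2.50), Clock (-1.71) and Nfil3 (-1.71). The difference of rhythm between PHx and sham had 19 genes.

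Samples were regrouped to see how many genes other groupings call. For PHx against sham there are 10 groupings per time, too few to exclude chance, and in each the real one alone (1 of 10) called as many genes. The highest other counts were 491, 0, 7, 1, 7, 6, 134 and 1 from 4 to 32 h. The same held for sham a day apart (1 of 10 each, highest others 172 and 1), for morning against night PHx at 4 h (1 of 10, 0), PHx at 24 h (1 of 10, 1) and sham at 24 h (1 of 10, 0), and for PHx against sham after night operation (1 of 10, 0). In sham at 4 h all 10 groupings called at least as many genes as the real 0, with 68 as the highest.

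With 100 groupings, chance is excluded for rhythm in sham (1 of 100 called as many as 3356, highest other 5) and after PHx (1 of 100, 1020 against 149). This covers random groupings of libraries and not the library ID series, which go with time and were not kept together in the regroupings. It does not show a 24 h period either, since any change with time, also one that does not repeat, can exceed such groupings. With the series as a covariate, 441 genes were called in sham and 1868 after PHx. For the difference of the PHx response 9 of 100 groupings called at least 59 genes, with 298 as the highest, so chance is not excluded. For the difference of rhythm 2 of 100 called at least 19, with 130 as the highest. In both differences another grouping called several times the real count. These regroupings did not hold the effects of morning against night, or of PHx against sham, fixed. Such an effect can then show up as a difference, so these regroupings cannot decide whether chance gave the calls.

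No gene was called between morning and night operation in sham at 4 h. An exchange of the columns numbered 3, with all other labels and numbers right, is excluded: time course sham 4 h replicate 3 would then match the column labelled night 3, but their correlation was -0.24. Together with other wrong numbers, such an exchange is not excluded. The grouping of morning 1 and 2 with night 3 called the 68 genes given above. With clock genes left out, 1 of 3 time course sham 4 h libraries (replicate 1) correlated best with a column labelled night (night 3, 0.35, next 0.09), and replicate 3 with the column labelled morning 1 (0.36, next 0.10), while all 9 libraries of the other 3 tables matched their own label (0.50 to 0.74). The column labelled morning 3 was the best match of none (highest 0.09). A wrong label of time course sham 4 h replicate 1, which lists 3422 genes at 0, would give the same match, so a wrong label of a column in this table stays open. Scaling is no explanation, since TMM factors gave 0 genes. Which labels are exchanged, if any, stays open, and they were kept as they are.

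Clock genes differ between sham 32 h and sham 8 h, the same clock time. The share of random lists with as large a median change was 1.0e-04, the smallest that 10000 lists can give (1.17 against 0.26). These lists were matched on expression alone. An offset between library series that is alike in all genes of like expression is thus excluded as the sole cause. A difference between series that falls on clock genes is not excluded, because series and time go together. Scaling is excluded (1.16 with TMM factors). A delay of the clock after the operation cannot be told apart from other causes: 13 of 13 called clock genes changed in the same direction after PHx, and 13 of 13 changed in the same direction in sham from 8 to 12 h. Without unoperated mice this stays open.

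Cell cycle genes of PHx 20 h replicate 2 and PHx 28 h replicate 2 lie apart from their groups (Mki67 at log2 4.1 against 0.3 and 0.4, and 0.1 against 4.2 and 2.7). An exchange of these 2 as finished libraries is excluded by genes that separate the library series: the share of the way to the other group was -0.25 for the first and 0.019 for the second. An exchange of animals or RNA before the libraries were made stays open, since these genes may follow the making of the library. Differences in timing between animals were not tested and stay open.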

How the results depend on the processing

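Alternatives were written before the data were examined, except the test on recovered reads at 4 h, the test of counts at 24 h and rhythm without sham 4 h replicate 1, which were added after seeing the data. The cause of a moved count was not tested. Of 399 named results 321 kept their call in every setting, 71 were weaker and 6 stronger in some, and 28 of the weaker ones only with a library left out. One reversed: Mki67 at 20 h, 0.40 with all libraries, was -0.84 without PHx 20 h replicate 2 and 1.03 without PHx 20 h replicate 1. A fit in which the low-value filter removed a gene may not be counted as a lost call, so 321 may be too high. For Per2 in morning against night PHx at 4 h, the highest adjusted p listed with a library left out was 0.046 (limma). Yet no gene was called without night PHx 4 h replicate 1.

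With the libraries of the comparison alone, PHx changed 3389 genes at 4 h (6077 in the fit of 48), 980 at 16 h (1770), 1541 at 20 h (2379) and 774 at 28 h (2659). With a fold limit of 1 log2, PHx changed 2290, 1113, 593, 580, 746, 561, 849 and 642 genes from 4 to 32 h. The sham comparisons a day apart then had 687 (4 to 28 h) and 434 (8 to 32 h) genes. Morning against night had 46 for PHx at 4 h and 345 for sham at 24 h, and PHx against sham after night operation had 1202. For morning against night PHx at 4 h, values as deposited gave 271 genes and recovered reads 88 (78 in the TMM fit). DESeq2 called 252 genes for morning against night PHx at 24 h (42 by edgeR), 1047 for sham at 24 h (661) and 243 for the difference of the PHx response (59).

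Rhythm in sham was called in 441 genes with the library ID series as a covariate (3356 without). After PHx it was called in 1868 with that covariate and in 3347 without 28 and 32 h (1020 with all). The difference of rhythm was called in 46 genes with TMM scaling, 12 with a pseudocount of 0.1, 105 with the series and 2371 without 28 and 32 h (19 in the planned fit).

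With an estimated correlation, the lists called went from 10 to 1, 8 to 1, 12 to 1, 14 to 3, 17 to 2, 15 to 1, 14 to 1 and 15 to 3 for PHx from 4 to 32 h. They went from 3 and 5 to 0 for sham a day apart at 28 and 32 h, from 8 (PHx) and 14 (sham) to 0 for morning against night at 4 h, and from 13 (PHx) and 7 (sham) to 0 at 24 h. After night operation they went from 12 to 0, and for the difference of the PHx response from 9 to 0.

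With 1 library left out, PHx changed 1384 (without PHx replicate 1) to 1750 genes at 12 h, 1130 (PHx 2) to 1770 at 16 h, 1566 (sham 3) to 2213 at 20 h, 1011 (sham 2) to 1409 at 24 h and 1116 (PHx 1) to 1602 at 32 h. Sham a day apart had 1706 (28 h replicate 1) to 2764 genes from 4 to 28 h and 1167 (32 h replicate 2) to 1399 from 8 to 32 h. Morning against night had 0 (night 1) to 48 (morning 1) for PHx at 4 h, 0 to 2 (morning 2) for sham at 4 h, 9 (morning 2) to 193 (night 2) for PHx at 24 h and 215 (morning 1) to 1022 (night 3) for sham at 24 h. The difference of the PHx response had 26 (morning PHx 1) to 130 (night PHx 2). Rhythm had 815 (without replicate 3) to 3869 (without sham 4 h replicate 1) genes in sham, 30 (replicate 3) to 138 (replicate 2) after PHx and 0 (replicate 3) to 32 (sham 4 h replicate 1) for the difference. Counts at 4, 8 and 28 h stayed at 5158 to 5775, 2388 to 2829 and 1856 to 2601.

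With the replicate number as a block (the replicate block), morning against night PHx had 21 genes at 4 h (78 without) and 14 at 24 h (42 without). Sham at 24 h, where deviations of samples with the same number correlated, had 790. The block changed no other count by over 1.5 times. It removed 17 named calls, added 0 and reversed 0. The labels do not say in any comparison that samples with the same number are paired.

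Depth was 24.6 to 30.2 M reads per library in the 24 h tables, and the filters leave genes with few reads untested there. The depth of the time course cannot be read from its values, so how far it limits calls of low genes was not assessed.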

Other observations

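All tests of this part were chosen after the results were seen. At 24 h after PHx, some genes were called after both morning and night operation: Ccnd1 rose by 2.83 ± 0.29 and 2.63 ± 0.30, Mki67 by 2.94 ± 0.64 and 2.61 ± 0.58, Saa2 by 8.91 ± 0.63 and 8.09 ± 0.43, and Thrsp fell by 3.79 ± 0.44 and 4.50 ± 0.56 (limma on the time course, edgeR on the night counts, 3 libraries per group). The values come from different units and were not compared with each other. Arntl rose by 2.83 ± 0.45 after night operation, and was at -0.28 ± 0.31 and not called after morning operation, which is not by itself a difference.

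The morning against night contrast at 24 h holds clock genes in both sham and PHx livers, with Npas2 at 5.80 ± 0.34 and 3.94 ± 0.36 and Tef at -2.52 ± 0.15 and -1.99 ± 0.14 (edgeR). Of the clock genes, Dbp (4.25 ± 0.77), Clock and Nfil3 were named for the difference between these contrasts, and Dbp lost its call in 6 of the fits with a library left out.

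A hypothesis was that PHx flattens the clock beyond other rhythmic genes. Of 18 clock genes 12 had a lower amplitude after PHx, with a median ratio of 0.84. Other genes rhythmic in sham, of like amplitude, had a median ratio of 0.70, and the share of random sets of such genes with as low a ratio as the clock genes was 0.93. The other genes were drawn for being called rhythmic in sham, which can lower their ratio, and the clock genes were not, so this test decides nothing and the hypothesis stays open.

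Pancreatic acinar genes marked 3 libraries of the time course: their mean log2 was 9.12 in PHx 4 h replicate 3, 7.31 in PHx 16 h replicate 3 and 4.24 in sham 24 h replicate 3, and at most 0.71 in the other 45. In the 24 h sham table, where 10 of them are listed, their mean log2(CPM + 1) was 9.43 in night sham 24 h replicate 3 and 4.07 in morning sham 24 h replicate 3, and at most 0.65 in the other 4 libraries. The other morning against night tables list only Cela1 of these genes. How pancreatic RNA came into these samples was not tested.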
